A study of Homo sapiens with 6 samples.

How the data were processed

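RNA was measured in neural progenitor cells made from H9, an established line of human embryonic stem cells. Per the labels' protocols, the cells were led toward midbrain dopamine neurons by dual-SMAD inhibition with 200 nM LDN193189 and 10 uM SB431542, and received 2 uM purmorphamine and 3 uM CHIR99021 during part of the culture. The labels give 2 groups of 3 biological replicates, unedited cells (WT) and cells with EPG5 knocked out with CRISPR-Cas9 (EPG5KO). The series design text names 1 knockout line and gives day 11 of differentiation for it. The day of the WT libraries is not given in the sources used here. No label says that the replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

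Total RNA was extracted with TRIzol and libraries were made with a stranded TruSeq mRNA kit, per the labels' protocols. Reads were trimmed with Trimmomatic, whose version is not given, and the genome build was GRCh38, per the submitters' processing notes. The aligner, the counting tool, its strand setting and the annotation are not given in the sources used here. The deposited values are FPKM, that is fragments scaled to transcript length and to the mapped fragments of the library, per the names of the deposited tables. FPKM is scaled within each library. The authors deposited WT and EPG5KO in separate tables, which list the same 35948 gene symbols in the same order with 6 decimals. Whether both tables came from a single run of the authors' pipeline is not given in the sources used here, and every level set across the 2 groups is also set across these tables. The tables hold 6 columns of values and all 6 were used. Of the genes listed, 10104 were at 0 in all libraries.

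The depth of the libraries is unknown, since FPKM keeps no read totals. The low values had no clear common step. The commonest ratio between libraries of values up to 0.08 FPKM, found in 15 to 26 of 1018 to 1113 genes compared, put the depth at 0.914 to 1.11 times that of WT replicate 1, which is a weak estimate. No intervals for counting error are given. The precision of each value is shown by the SD over 3 libraries. FPKM summed to between 345671 and 379022 per library.

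The test was limma (version 3.58.1, with statmod 1.5.0, in R 4.3.3) on log2(FPKM + 1), with empirical Bayes moderation that follows the intensity trend, 2 groups, no other term, and Benjamini-Hochberg adjustment over the genes tested. Genes with at least 1 FPKM in at least 3 of the 6 libraries were tested, 13653 in all. A gene changed if its adjusted p was below 0.05. The pseudocount of 1 makes log2 differences understate the change of genes with low values. Means are given with the SD over 3 libraries per group, and log2 differences with the standard error (SE) from limma or its 95% confidence interval. EPG5 was also tested with an exact permutation test.

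The 33 gene lists were written before the data were examined and tested with camera (limma) with a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with a correlation estimated for each list and fry (limma) were run beside it. With the estimated correlation, 0 of the 33 lists passed and the adjusted p lay between 0.174 and 0.979, so no list call below holds under that setting. The estimate was 0.0101 for the forebrain list and 0.0025 for the hindbrain list, near or under the preset. Their adjusted p still rose to 0.174 and 0.433, so a higher correlation within the lists does not alone account for the lost calls. With an estimated correlation, camera is also stricter, since its degrees of freedom then come from the 6 libraries and not from the genes. A list that did not pass under that setting is thus not shown to be unchanged. Fry called 20 lists, without 5 of the 18 that camera called and with 7 others. For each list, the genes that rose or fell over all genes tested are counted, and again with the adjustment made over the list alone.

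The genes named in the text follow a rule fixed before the data were examined. It takes EPG5, the 8 highest and 8 lowest differences among changed genes with a mean of at least 5 FPKM and no overlap between the groups, up to 4 members with the smallest adjusted p of each called list, of the 3 WNT lists and of the autophagy list, and 18 genes chosen in advance for the WNT/DVL pathway, autophagy, pluripotency and neural identity. Of these last, EN1, PAX6, NANOG and POU5F1 were below the filter and were not tested. The rule gave 110 genes, some of which are not reported here. XIST and Y-linked genes were left out of it. Other genes are said to have been chosen after their values were seen or to lie outside the rule.

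Gene positions are from GENCODE v29 on GRCh38, which may differ from the annotation the authors used. Of the 108 named genes found there, 22 share over 10% of their exonic bases with another annotated gene on either strand, and their values are uncertain where the counting could split or join reads: MAB21L2, FEZF1, NUSAP1, PLK1, AXIN2, NDUFA1, ACAT2, NQO1, IDS, CD68, HMGCS1, TUBB3, WIPI1, IFITM1, SQSTM1, PDGFRA, JUNB, NEFL, NKX2-2, NEFM, CRABP1 and UBD. HSPA1A and the HLA genes have near-identical relatives and are uncertain for that reason.

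Replicates with the same number in the 2 groups deviated together. Across the tested genes, the deviations from the group means correlated at 0.14, 0.30 and 0.22 for the 3 pairs with the same number, against at most 0.05 for the others. The numbers come from the labels and were taken to pair the libraries, and a fit with the replicate number as a block was run beside the unpaired fit. No pair of libraries within a group was identical, with 3 to 7 tested genes at the same value in both.

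The script was tested on simulated data for the comparison of EPG5KO with WT, with 200 seeded genes among 13653. It recovered 56% of genes changed by 0.5 on the log2 scale, 96% of those changed by 1 and 100% of those changed by 2 or 3, and 3.30% of its calls were false. The seeded genes were a smaller share than the 19.5% called in the data. No replicate pairing and no length or GC trend was simulated. The shares recovered and falsely called thus need not hold for the data. A simulated list shifted by 0.3 gave a camera p of 1.57e-34 and an unshifted list gave 0.456. The simulated noise was independent between genes, whereas the correlation estimated for the real lists reached 0.94. The simulation therefore does not test camera on lists whose genes move together.

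The alternatives chosen before the data were examined were pseudocounts of 0.1 and 0.5, no filter on low values, a mean of at least 5 FPKM, quantile normalization, median-ratio scaling, no intensity trend, robust estimation with array weights, the replicate block, and each library left out in turn. The array weights were 0.467, 0.196 and 3.82 for WT replicates 1, 2 and 3. They were 3.79, 0.760 and 0.993 for EPG5KO replicates 1, 2 and 3. Every result with array weights thus rests mostly on WT replicate 3 and EPG5KO replicate 1. Removal of the length and GC trend from each library within the replicate block, and camera with an estimated correlation within the block, were added after the data were seen. Transcript length and GC content were taken from the longest GENCODE transcript of each symbol and were found for 96.8% of the genes tested, but for 0% of the mitochondrially encoded list, which that correction left as it was. The edit in EPG5 was not analysed here, since FPKM values carry no sequence.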

Results

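Gene expression was measured by RNA sequencing in neural progenitor cells differentiated from H9 human embryonic stem cells toward midbrain dopamine neurons, 3 libraries from unedited cells (WT) and 3 from cells in which EPG5 had been knocked out (EPG5KO). EPG5 is a tethering protein needed for the fusion of autophagosomes with lysosomes. The series concerns how autophagy bears on neuronal differentiation and on the WNT/DVL pathway, and the comparison of EPG5KO with WT asks which genes differ between these progenitors. All knockout libraries came from 1 edited line, so differences between that line and its parent cells are part of every comparison. Log2 expression correlated between 0.987 and 0.994 across genes within WT, between 0.994 and 0.996 within EPG5KO and between 0.965 and 0.979 across the groups, where genes are not independent replicates. The first principal component held 68.3% of the variance and parted the groups. The second held 15.3% and set WT replicate 2 apart at -16.1, against 13.4 and 6.60 for the other WT libraries. In WT replicate 2, deviations from the mean of the libraries correlated across genes with transcript length at a Spearman's rho of -0.44 and with GC content at 0.34, while the rho for length lay between -0.02 and 0.27 in the other libraries.

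EPG5 itself, on chromosome 18 from 45847609 to 45967339 (GRCh38), was listed at 3.01, 2.06 and 3.05 FPKM in the WT libraries and at 2.41, 2.22 and 2.39 FPKM in the EPG5KO libraries. The mean was 2.71 ± 0.560 FPKM in WT and 2.34 ± 0.103 FPKM in EPG5KO (SD, n = 3 each). The log2 difference was -0.14 with a 95% confidence interval from -0.40 to 0.12 and an adjusted p of 0.444 in limma, and an exact 2-sided permutation test gave p = 0.4, where the smallest p that 3 against 3 libraries allow is 0.1. Without WT replicate 2, the difference was -0.27 with an adjusted p of 0.0448, and with array weights it was -0.24 with an adjusted p of 0.00973. Without WT replicate 1 or 3, the EPG5 level differed by -0.08 and -0.07, with adjusted p of 0.699 and 0.756. An edit that disrupts the protein need not lower the RNA, so these values do not check which libraries carry the edit.

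Of 13653 genes tested, 2667 (19.5%) changed between EPG5KO and WT, 1258 higher and 1409 lower in EPG5KO. The change was at least 2-fold on the log2(FPKM + 1) scale for 276 genes, 103 higher and 173 lower. The 2 groups did not overlap for 39.6% of the genes tested, where chance gives 10%. The count was 1521 without EPG5KO replicate 1, 1489 without EPG5KO replicate 3 and 1570 among genes with a mean of at least 5 FPKM, the higher count was 809 without WT replicate 3, and the count rose to 4140 after removal of the length and GC trend within the replicate block. With array weights, 6260 genes passed, of which 58.8% were higher, against 47.2% of the 2667, and a pseudocount of 0.1 put 505 genes past 2-fold, 164 higher and 341 lower. The fit with array weights rests mostly on WT replicate 3 and EPG5KO replicate 1, whose weights were 3.82 and 3.79.

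On the log2(FPKM + 1) scale the largest rise was that of NNAT, an imprinted gene that codes for the membrane proteolipid neuronatin and lies within an intron of BLCAP. NNAT, on chromosome 20 from 37521206 to 37523693, went from 2.89 ± 0.163 FPKM in WT to 122.5 ± 6.07 FPKM in EPG5KO (SD, n = 3 each), a log2 difference of 4.99 (SE 0.07, adjusted p = 6.75e-10). NLRP2, a gene of the NLR family on chromosome 19 from 54953130 to 55001142, rose from 0.178 ± 0.0682 to 12.4 ± 0.684 FPKM (log2 difference 3.50, adjusted p = 5.70e-08), and by the ratio of mean FPKM it rose more than NNAT, 69.3-fold against 42.5-fold. MYL4, a myosin light chain gene of the embryonic heart, rose from 13.0 ± 2.84 to 115.8 ± 15.1 FPKM. The secreted EGF-domain gene EGFL6 rose by 2.32 on the log2 scale, the developmental gene MAB21L2 by 2.21 and the collagen gene COL22A1 by 2.04. RGS5 and RGS4, which lie side by side on chromosome 1 and code for regulators of G protein signalling, rose by 2.04 and 1.98.

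On the same scale, the largest fall among genes with a mean of at least 5 FPKM was that of UBD, which codes for the ubiquitin-like modifier FAT10 and lies on chromosome 6 from 29555515 to 29559925. UBD went from 16.1 ± 1.34 FPKM in WT to 1.54 ± 0.210 FPKM in EPG5KO (log2 difference -2.75, SE 0.09, adjusted p = 3.57e-07), and 76.9% of its exonic bases are shared with other annotated genes. Among genes with lower means, TYW3 (-2.80) and PNPLA4 (-2.76), chosen after their values were seen, fell further. CRYZ, the quinone reductase zeta-crystallin on chromosome 1 from 74705482 to 74733408, went from 14.2 ± 1.34 to 1.86 ± 0.226 FPKM (log2 difference -2.41, adjusted p = 9.99e-07). On the other strand, 6.29% of the exonic bases of CRYZ are shared, chiefly with TYW3, so both falls lie at the same locus. The readthrough transcript CZ1P-ASNS fell by 2.14 while ASNS, whose exons it shares, differed by 0.14 with an adjusted p of 0.394, so the level of CZ1P-ASNS is uncertain. The neuropeptide gene NTS fell by 2.13, the polyamine acetyltransferase gene SAT1 by 2.10 and the protease-activated receptor gene F2RL1 by 2.01. CRABP1, which codes for a retinoic acid binding protein and is an abundant transcript here, went from 250.3 ± 77.5 to 60.6 ± 8.52 FPKM.

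**Figure D1:**
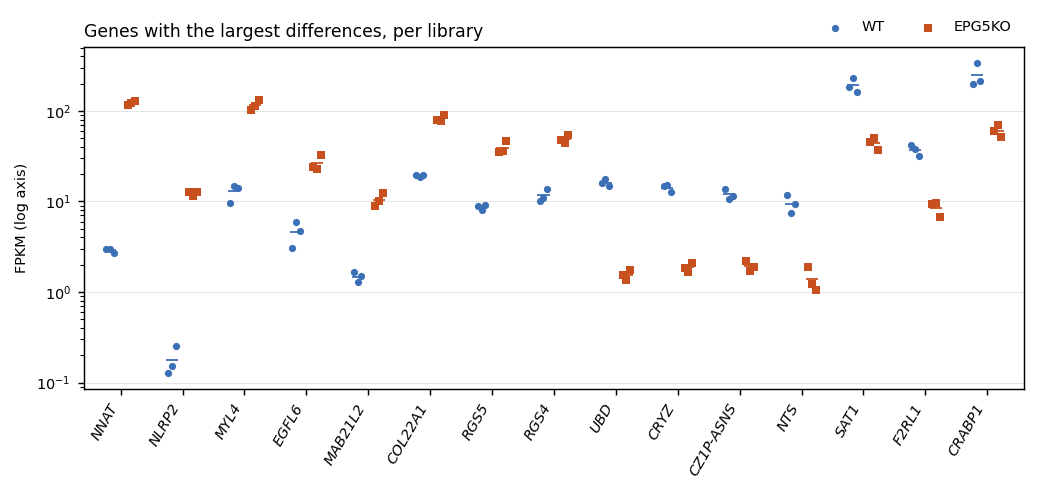
FPKM of 8 genes with the highest and 7 of the 8 with the lowest log2 differences among changed genes with a mean of at least 5 FPKM, on a log axis. Each point is a library, 3 WT (circles) and 3 EPG5KO (squares) per gene, and the line is the group mean; NNAT lies near 2.89 FPKM in WT and near 122.5 FPKM in EPG5KO.

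Genes of neuronal differentiation were lower in EPG5KO. Of 32 neuron genes tested, 21 fell and 0 rose (23 and 1 adjusted over the list alone), with a median difference of -0.67. GAP43, a growth cone protein gene, went from 26.9 ± 3.88 to 8.84 ± 1.12 FPKM, and the neurofilament genes NEFM and NEFL fell by 1.55 and 1.01. TAGLN3 fell by 1.06 and TUBB3, the gene of neuronal beta-tubulin, by 0.63. DCX, a marker of young neurons, was at 4.30 ± 1.70 FPKM in WT and 2.85 ± 0.455 FPKM in EPG5KO with an adjusted p of 0.212, which became 0.0132 with the replicate block and 0.00777 without WT replicate 2. The camera adjusted p of the list was 2.01e-11, and adjusted p = 0.439 with an estimated correlation. Relative to the WT mean, the list's median was 0.21, -0.22 and 0.03 in the WT libraries and between -0.73 and -0.57 in the EPG5KO libraries, WT replicate 2 being the lowest of the WT libraries. Without WT replicate 1, 2 of them rose, and without a filter on low values the median over 51 was -0.42. Synapse genes did not pass as a list. Of 27 tested, 4 rose and 8 fell (6 and 11 adjusted over the list alone), with a median of -0.13, an adjusted p of 0.112 and adjusted p = 0.646 with an estimated correlation, although without a filter on low values the adjusted p was 0.0180. The number that rose was 6 without WT replicate 1, 1 without WT replicate 3 and 0, 1 and 1 in limma without EPG5KO replicate 1, 2 or 3. Without EPG5KO replicate 3, 5 fell and the median was -0.07.

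Cell cycle genes were higher in EPG5KO. Of 50 tested, 31 rose and 0 fell (35 and 0 adjusted over the list alone), with a median difference of 0.28 and a camera adjusted p of 2.01e-11 (adjusted p = 0.433 with an estimated correlation). CENPA, the centromeric histone gene, went from 6.32 ± 0.234 to 10.2 ± 0.606 FPKM. KIF20A, a mitotic kinesin gene, rose by 0.59, the spindle gene NUSAP1 by 0.46 and the mitotic kinase gene PLK1 by 0.43. Fewer of the 50 passed singly when a library was left out, down to 11 without EPG5KO replicate 3, 12 without EPG5KO replicate 1 and 17 without WT replicate 3.

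Forebrain genes were higher in EPG5KO. Of 10 tested, 8 rose and 0 fell (8 and 1 adjusted over the list alone), with a median difference of 1.00. SIX3, a transcription factor gene of the anterior neural plate, went from 0.369 ± 0.140 to 5.45 ± 0.242 FPKM, and FEZF1 from 0.402 ± 0.0769 to 2.91 ± 0.501 FPKM. OTX1 rose by 1.34 and WNT8B by 1.39 (2.90-fold and 3.49-fold by the ratio of mean FPKM). Without a filter on low values, which adds members with low values, the median over 26 was 0.04. The list's adjusted p was 2.92e-07, and adjusted p = 0.174 with an estimated correlation. Among hindbrain, spinal cord and HOX genes, 3 of 9 rose and 6 fell (3 and 6 adjusted over the list alone), with a median of -0.59. EGR2, a gene of hindbrain segments, went from 2.90 ± 0.528 to 0.465 ± 0.121 FPKM. NKX2-2, a gene of ventral progenitors, fell by 1.11, which is 4.93-fold by the ratio of mean FPKM. DBX1, which marks progenitors at intermediate dorsoventral levels, went the other way, from 48.6 ± 8.46 to 159.2 ± 14.0 FPKM. Without a filter, 10 of 28 fell with a median of -0.13. This list passed narrowly at an adjusted p of 0.0413, with adjusted p = 0.433 with an estimated correlation, and the call was lost with the replicate block (adjusted p = 0.0611), without WT replicate 1, 2 or 3 (0.0510, 0.0926 and 0.0543), with a pseudocount of 0.1 (0.0502), with array weights (0.0707) and with the length and GC trend removed (0.148).

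Midbrain floor plate and dopaminergic progenitor genes moved both ways. Of 22 tested, 9 rose and 4 fell (10 and 4 adjusted over the list alone), with a median of 0.19, an adjusted p of 0.0865 and adjusted p = 0.655 with an estimated correlation. Without WT replicate 2, 7 fell and the median was 0.12, with array weights 7 fell, and without a filter the median over 38 was 0.01. The adjusted p was 0.0236 without WT replicate 3, 2.95e-04 among genes with a mean of at least 5 FPKM and 0.0382 with the length and GC trend removed. FOXA2, a transcription factor gene of the floor plate, was at 40.2 ± 0.872 FPKM in WT and 44.1 ± 1.41 FPKM in EPG5KO (log2 difference 0.13, 95% confidence interval -0.01 to 0.26, adjusted p = 0.171). LMX1A was at 42.9 ± 4.42 and 49.0 ± 3.81 FPKM (log2 difference 0.19, adjusted p = 0.176). Both passed with array weights and with the length and GC trend removed. OTX2, a gene of forebrain and midbrain, rose by 0.48 from 72.2 ± 2.76 to 101.0 ± 2.39 FPKM. EN1, a gene of the midbrain and hindbrain boundary, was under the filter at 0.734 ± 0.0730 FPKM in WT and 0.108 ± 0.0250 FPKM in EPG5KO and was not tested. Chosen after their values were seen, LMX1B rose by 1.14 and LMO3 by 1.12, while the floor plate gene CORIN fell by 1.75 and CALB1 by 1.63.

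Neural progenitor and radial glia genes, 29 tested, gave 6 that rose and 13 that fell (9 and 13 adjusted over the list alone), a median of -0.13 and an adjusted p of 0.112 (adjusted p = 0.439 with an estimated correlation, and 0.00897 downward in fry). The median was -0.08 without WT replicate 1 and -0.08 without EPG5KO replicate 3. SOX2, a transcription factor gene of neural progenitors, fell by 0.22, from 83.5 ± 4.15 to 71.5 ± 1.43 FPKM, with an adjusted p of 0.0409, a call that was lost without WT replicate 1 (0.0840), without EPG5KO replicate 1, 2 or 3 (0.136, 0.110 and 0.168) and without the intensity trend (0.0606). PAX6, a forebrain and hindbrain progenitor gene, was under the filter at 0.151 ± 0.0603 FPKM in WT and 0.590 ± 0.0670 FPKM in EPG5KO. Pluripotency genes gave 3 that rose and 2 that fell of 10 (4 and 2 adjusted over the list alone), with a median of 0.06, a mean of -0.01 and a camera test that pointed up at an adjusted p of 0.524 (adjusted p = 0.655 with an estimated correlation). Their median was 0.13 without WT replicate 1 and 0.09 without EPG5KO replicate 2. POU5F1 and NANOG, core genes of pluripotent cells, were below 0.1 FPKM in all 6 libraries.

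The WNT pathway was compared at 3 levels, and none of the 3 lists passed camera. Among WNT/beta-catenin feedback and target genes, 5 of 24 rose and 6 fell (7 and 6 adjusted over the list alone), with a median of -0.05, an adjusted p of 0.691 and adjusted p = 0.742 with an estimated correlation. AXIN2, a direct feedback target, was at 23.3 ± 1.10 FPKM in WT and 22.1 ± 1.62 FPKM in EPG5KO (log2 difference -0.07, 95% confidence interval -0.24 to 0.09), and LEF1, which codes for a partner of beta-catenin, at 9.93 ± 0.364 and 9.75 ± 0.229 FPKM (log2 difference -0.02, 95% confidence interval -0.17 to 0.12). Members that changed went both ways, with CD44 falling by 1.61, MSX1 by 0.84 and SNAI2 by 0.82 and with AMOTL2 rising by 0.93. For the LEF1 difference, the sign turned without WT replicate 1 (0.0023). The median was -0.02 without WT replicate 2 and -0.08 without WT replicate 3. The test of this list pointed up among genes with a mean of at least 5 FPKM, with an adjusted p of 0.240.

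Of 30 WNT ligands, receptors and secreted regulators, 9 rose and 5 fell (10 and 6 adjusted over the list alone), with a median of 0.13, an adjusted p of 0.146 and adjusted p = 0.496 with an estimated correlation. Without WT replicate 1, EPG5KO replicate 1 or EPG5KO replicate 3, 3 fell, and 7 fell without WT replicate 2, with a median of 0.08. With array weights 14 rose and 8 fell. The receptor genes FZD8 and FZD5 rose, FZD8 from 2.70 ± 0.254 to 8.86 ± 0.513 FPKM and FZD5 from 2.68 ± 0.0635 to 5.40 ± 0.266 FPKM. WNT8B rose from 1.94 ± 0.195 to 6.75 ± 1.13 FPKM. ROR2, a receptor gene of noncanonical WNT signals, fell from 6.53 ± 0.174 to 2.99 ± 0.162 FPKM. Fry, which asks whether a list moves on balance one way without comparing it with other genes, called this list at an adjusted p of 0.00901.

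Of 39 genes of cytoplasmic WNT signal transduction, 5 rose and 4 fell (6 and 4 adjusted over the list alone). The median was -0.03, the mean 0.00 and the adjusted p 0.950 (adjusted p = 0.979 with an estimated correlation), with a mean and a test of opposite sign. Without WT replicate 2, 7 fell and the median was -0.06, and without WT replicate 1 the median was 0.01. Without EPG5KO replicate 1 or 3, 3 rose and 2 fell, and 2 fell without EPG5KO replicate 2, with a median of -0.02. With array weights 10 rose and 10 fell, and with the replicate block 8 rose. The Dishevelled genes, whose proteins pass the signal on from Frizzled receptors, differed little in RNA, which does not show their protein levels. DVL1 was at 9.99 ± 1.72 FPKM in WT and 9.42 ± 0.510 FPKM in EPG5KO (log2 difference -0.07, 95% confidence interval -0.31 to 0.18), and the sign turned without WT replicate 2 (0.06). DVL3 was at 21.8 ± 1.38 and 22.6 ± 0.386 FPKM (log2 difference 0.05, 95% confidence interval -0.10 to 0.20). DVL2 rose from 23.8 ± 0.868 to 27.6 ± 0.971 FPKM (log2 difference 0.20, 95% confidence interval 0.06 to 0.35) with an adjusted p of 0.0498. That call was lost without WT replicate 1 or 3 (0.0707 and 0.134), without EPG5KO replicate 1, 2 or 3 (0.175, 0.0857 and 0.203), with pseudocounts of 0.1 and 0.5 (0.0503 and 0.0501), with a mean of at least 5 FPKM (0.0563) and without the intensity trend (0.0731). CTNNB1, the gene of beta-catenin, fell by 0.34, from 197.4 ± 2.94 to 155.4 ± 6.84 FPKM, and the corepressor gene TLE1 fell by 0.41. TCF7L2 and TCF7L1, transcription factor genes of the pathway, rose by 0.47 and 0.32.

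Autophagy genes were lower as a list in EPG5KO at the level of RNA, which shows neither the protein levels nor the activity of autophagy. Of 57 tested, 2 rose and 11 fell (3 and 11 adjusted over the list alone), with a median difference of -0.09, an adjusted p of 0.0121 and adjusted p = 0.439 with an estimated correlation. VAMP8, a SNARE gene of the fusion of autophagosomes with lysosomes, went from 11.2 ± 2.03 to 2.59 ± 0.594 FPKM (log2 difference -1.76, adjusted p = 4.94e-05). SQSTM1, the gene of the autophagy receptor p62, went from 33.6 ± 5.94 to 17.8 ± 0.834 FPKM, and MAP1LC3B, whose protein is lipidated on autophagosomes, from 56.2 ± 5.91 to 39.5 ± 1.50 FPKM. WIPI1 fell by 0.72. Without EPG5KO replicate 1, 2 or 3, the number that fell was 4, 6 and 5 and the number that rose 0, 1 and 0 in limma, and 4 and 1 rose without WT replicate 1 or 3. With array weights 5 rose and 18 fell. Lysosome genes were lower too, with 3 of 63 rising and 16 falling (3 and 17 adjusted over the list alone), a median of -0.13 and an adjusted p of 0.00217 (adjusted p = 0.439 with an estimated correlation). Without EPG5KO replicate 1, 2 or 3, 7, 5 and 5 of them fell and 1 rose each time, and 5 rose without WT replicate 2. With array weights 7 rose and 25 fell. The acid lipase gene LIPA fell by 0.72, the proton pump gene ATP6V0D1 by 0.54 and IDS by 0.49. MITF, a transcription factor gene of pigment cells in this list, rose from 0.661 ± 0.124 to 3.10 ± 0.192 FPKM.

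**Figure D2:**
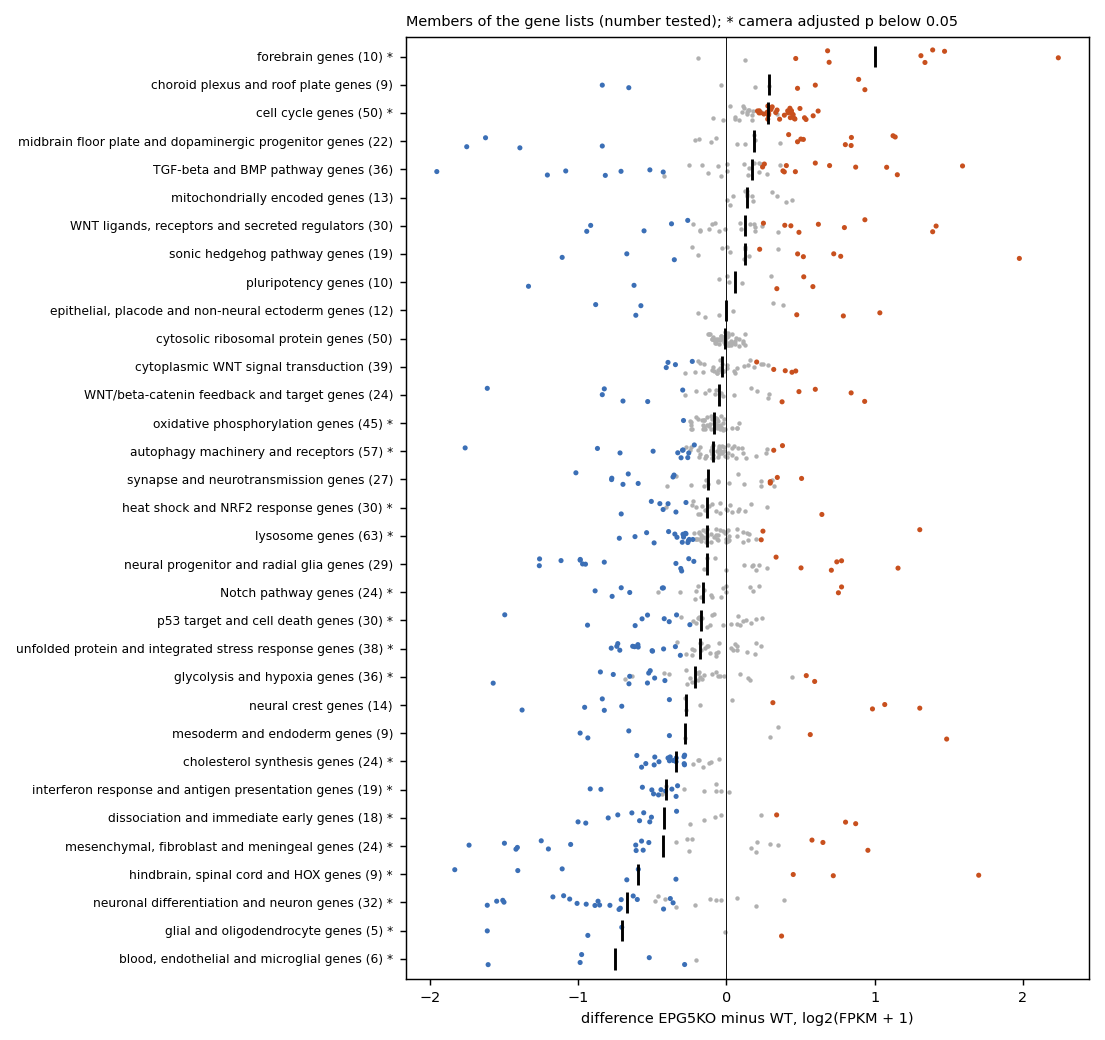
Log2 difference of each tested member of the 33 gene lists, EPG5KO minus WT, on the log2(FPKM + 1) scale, with the number tested in parentheses. Coloured points are genes that changed, grey points those that did not pass, and the bar is the list's median, from -0.75 for blood and endothelial genes to 1.00 for forebrain genes; stars mark the 18 lists called by camera with the preset correlation.

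Cholesterol synthesis genes were lower in EPG5KO. Of 24 tested, 16 fell and 0 rose (19 and 0 adjusted over the list alone), with a median of -0.34 and an adjusted p of 6.70e-09 (adjusted p = 0.433 with an estimated correlation). FDFT1, the squalene synthase gene, went from 49.7 ± 2.13 to 33.7 ± 1.53 FPKM and HMGCS1 from 35.0 ± 4.16 to 23.1 ± 0.990 FPKM. SREBF2, the gene of the transcription factor that drives this pathway, fell by 0.46 and ACAT2 by 0.38. The number that fell was 7, 10 and 7 without EPG5KO replicate 1, 2 or 3. Of 19 interferon response and antigen presentation genes, 11 fell and 0 rose (14 and 0 adjusted over the list alone), with a median of -0.41 and an adjusted p of 1.25e-06 (adjusted p = 0.433 with an estimated correlation). BST2 fell by 0.92, IFITM1 by 0.85, B2M by 0.57 and the peptide transporter gene TAP1 by 0.49. Without EPG5KO replicate 1 or 2, 7 of these fell, and without a filter the median over 35 was -0.13.

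Stress response lists were lower in camera, while fry did not call those of the unfolded protein response (0.188), of heat shock and NRF2 (0.0658) and of dissociation (0.107). Of 30 p53 target and cell death genes, 9 fell and 0 rose (10 and 0 adjusted over the list alone), with a median of -0.17 and an adjusted p of 0.00217 (adjusted p = 0.439 with an estimated correlation). GDF15, a stress-induced cytokine gene, went from 18.6 ± 4.40 to 5.97 ± 1.65 FPKM, and CDKN1A, the gene of the cell cycle inhibitor p21, from 64.1 ± 3.93 to 42.9 ± 1.16 FPKM. SPATA18 fell by 0.94 and PLK3 by 0.53. With array weights 7 rose and 13 fell, without WT replicate 2 the median was -0.10, and 1 rose without WT replicate 1 or 2. Of 38 genes of the unfolded protein and integrated stress responses, 13 fell and 0 rose (13 and 1 adjusted over the list alone), with a median of -0.18 and an adjusted p of 0.00174 (adjusted p = 0.599 with an estimated correlation). The chaperone gene HSP90B1 fell by 0.63, PDIA4 by 0.74, MANF by 0.60 and DNAJC3 by 0.50. This list's median relative to the WT mean was 0.22 in WT replicate 2, the library that stood apart, and -0.07 and -0.12 in the other WT libraries. Its median difference was -0.09 without WT replicate 2, -0.29 without WT replicate 3, -0.27 without EPG5KO replicate 2 and -0.09 without EPG5KO replicate 3. Of its members, 5 rose and 14 fell with array weights, 7 fell without EPG5KO replicate 1 or 3, and 2 rose without WT replicate 2. Of 30 heat shock and NRF2 response genes, 1 rose and 7 fell (1 and 8 adjusted over the list alone), with a median of -0.13, an adjusted p of 0.0173 and adjusted p = 0.496 with an estimated correlation. HMOX1 fell by 0.71 and NQO1 by 0.39, while HSPA1A rose by 0.64. Of this list, 4 fell without WT replicate 3, and 2, 3 and 4 fell without EPG5KO replicate 1, 2 or 3, with 2 that rose without EPG5KO replicate 2. With array weights 3 rose and 13 fell, with a median of -0.03. Its call was lost without EPG5KO replicate 2 (0.0625), and the NQO1 call without EPG5KO replicate 1 (0.0576). Of 18 dissociation and immediate early genes, 3 rose and 10 fell (3 and 11 adjusted over the list alone), with a median of -0.42 and an adjusted p of 0.00753 (adjusted p = 0.496 with an estimated correlation). JUNB fell by 1.00 and NFKBIA by 0.56, while CCN1 rose by 0.87 and SOCS3 by 0.80. Without EPG5KO replicate 3, 6 of them fell.

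Genes of energy metabolism differed in part. Of 36 glycolysis and hypoxia genes, 2 rose and 10 fell (2 and 11 adjusted over the list alone), with a median of -0.21 and an adjusted p of 0.00217 (adjusted p = 0.645 with an estimated correlation, and 0.296 in fry). NDRG1, a hypoxia-induced gene, went from 76.4 ± 21.5 to 24.8 ± 5.87 FPKM and PFKP fell by 0.52. LDHA, the lactate dehydrogenase gene, went the other way, from 727.7 ± 51.2 to 1100 ± 86.8 FPKM, and HK1 rose by 0.54. The list's median relative to the WT mean spread from -0.21 to 0.15 over the WT libraries and from -0.49 to -0.09 over the EPG5KO libraries. The median difference was -0.35 without WT replicate 3 and -0.33 without EPG5KO replicate 2. With array weights 4 rose and 11 fell, with a median of -0.09. With the replicate block 17 fell, and 6, 4 and 4 fell without WT replicate 1, EPG5KO replicate 1 or EPG5KO replicate 3. Of 45 oxidative phosphorylation genes, SDHB fell by 0.29 and no other member passed (0 rose and 0 fell adjusted over the list alone), with a median of -0.09, an adjusted p of 0.00628, adjusted p = 0.655 with an estimated correlation and 0.317 in fry. With the replicate block 6 fell, with quantile normalization 4 (median -0.05), and with array weights 8 fell and 3 rose (median -0.05). The number that fell was 3, 2 and 2 without WT replicate 1, 2 or 3 and 0 in limma without any 1 of the EPG5KO replicates. The list's median was 0.15 in WT replicate 2 against -0.09 and -0.05 in the other WT libraries, and without WT replicate 2 the call was lost (0.257) with a median difference of -0.01, against -0.14 without WT replicate 1. NDUFA1, NDUFA8 and COX7A2 had adjusted p of 0.0519, 0.0655 and 0.0742, and of 0.0245, 0.0325 and 0.0366 with the replicate block. The SDHB call was lost without WT replicate 1 (0.0510), without EPG5KO replicate 1, 2 or 3 (0.0734, 0.0598 and 0.127) and without a filter (0.0630). Mitochondrially encoded genes, 13 tested, gave 0 calls in limma (0 adjusted over the list alone, 4 at an unadjusted p under 0.05), while 4 rose with the replicate block, 3 with array weights, where the median turned to -0.02, and 1 without the intensity trend or without WT replicate 1. They had a median of 0.14 and an adjusted p of 0.0839 (adjusted p = 0.655 with an estimated correlation). The median was -0.04 without EPG5KO replicate 3, 0.25 without WT replicate 3 and 0.28 without EPG5KO replicate 2. The adjusted p was 0.0310 with the replicate block, 0.00782 with the length and GC correction, which did not reach these genes, 0.0168 without WT replicate 3, 0.0379 without EPG5KO replicate 1 and 0.0125 without EPG5KO replicate 2. Of 50 cytosolic ribosomal protein genes, 0 changed in limma (0 adjusted over the list alone, 0 at an unadjusted p under 0.05), although 3 rose with array weights and 4 without WT replicate 2, with a median of -0.01, an adjusted p of 0.770 and adjusted p = 0.979 with an estimated correlation. Their median was 0.20 in WT replicate 2 and -0.14 and -0.06 in the other WT libraries. The median difference was -0.08, 0.10 and -0.04 without WT replicate 1, 2 or 3, -0.03 without EPG5KO replicate 2 and 0.02 without EPG5KO replicate 3. Without WT replicate 1 the list passed downward (0.0274), and without WT replicate 2 it passed upward (5.62e-04).

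Genes of other cell types were measured beside these. Of 24 mesenchymal, fibroblast and meningeal genes, 3 rose and 12 fell (5 and 15 adjusted over the list alone), with a median of -0.43 and an adjusted p of 2.49e-04 (adjusted p = 0.439 with an estimated correlation). Without WT replicate 2, and with array weights, 6 rose, and without a filter the median over 29 was -0.27. The collagen genes COL1A2, COL6A2 and COL6A3 fell, COL1A2 by 1.25, COL6A2 by 1.50 and COL6A3 by 1.20, and LGALS1 fell by 1.42. Of 6 blood, endothelial and microglial genes, 5 fell and 0 rose (5 and 0 adjusted over the list alone), with a median of -0.75 and an adjusted p of 8.96e-05 (adjusted p = 0.433 with an estimated correlation). FLT1 and KDR, receptor genes for VEGF, fell by 1.61 and 0.99 (4.66-fold and 5.04-fold by the ratio of mean FPKM) and ESAM by 0.98. Without EPG5KO replicate 3, 3 of the 6 fell, and without a filter, which adds members with low values, the median over 19 was -0.08. CD68 fell by 0.52, a call lost without EPG5KO replicate 3 (0.0578) and without a filter (0.0641). Of 5 glial and oligodendrocyte genes, 1 rose and 3 fell (1 and 3 adjusted over the list alone), with a median of -0.71 and an adjusted p of 0.0277 (adjusted p = 0.439 with an estimated correlation). PDGFRA fell by 0.94 and CD44, which is also in the WNT target list, as given above, while GJA1 rose by 0.37, a call lost without EPG5KO replicate 1 or 3 (0.0719 and 0.0733). Without EPG5KO replicate 1 or 3, 0 rose in limma. Without a filter the median over 20 was -0.01. This list was lost without a filter (0.164) and with the length and GC trend removed (0.0770).

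Neural crest genes, 14 tested, gave 4 that rose and 6 that fell (4 and 8 adjusted over the list alone), a median of -0.28 and an adjusted p of 0.0984 (adjusted p = 0.439 with an estimated correlation). With array weights the adjusted p was 0.0445, and in fry 0.00162, downward. Without a filter the median over 26 was -0.01. Mesoderm and endoderm genes, 9 tested, gave 2 that rose and 4 that fell (4 and 5 adjusted over the list alone), a median of -0.28 and an adjusted p of 0.501 (adjusted p = 0.646 with an estimated correlation, and 0.0457 downward in fry). The number that rose was 4 without WT replicate 2 and 1 without EPG5KO replicate 1, and without a filter the median over 33 was -0.01. Epithelial, placode and non-neural ectoderm genes, 12 tested, gave 3 that rose and 3 that fell (5 and 3 adjusted over the list alone). Their median was just under 0 and their mean 0.05, the test pointed up at an adjusted p of 0.673, and adjusted p = 0.870 with an estimated correlation. The median lay on both sides of 0 when a library was left out, at -0.05, 0.05 and -0.01 without WT replicate 1, 2 or 3 and 0.04, -0.03 and -0.02 without EPG5KO replicate 1, 2 or 3. Choroid plexus and roof plate genes, 9 tested, gave 4 that rose and 2 that fell (5 and 2 adjusted over the list alone), a median of 0.29 and an adjusted p of 0.0647 (adjusted p = 0.439 with an estimated correlation). Their adjusted p was 0.0337 without WT replicate 3, 0.0470 without EPG5KO replicate 1, 0.0128 among genes with a mean of at least 5 FPKM, 0.0455 with the length and GC trend removed and 0.00901 in fry. Without a filter the median over 21 was 0.04.

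Of 24 Notch pathway genes, 2 rose and 6 fell (3 and 7 adjusted over the list alone), with a median of -0.16, an adjusted p of 0.0290 and adjusted p = 0.450 with an estimated correlation. The ligand genes DLL1 and JAG1 fell by 0.71 and 0.65, the target gene HEY1 by 0.89 (3.00-fold by the ratio of mean FPKM) and LFNG, the gene of a glycosyltransferase that modifies Notch, by 0.77. The call was lost without WT replicate 1 (0.0729), without EPG5KO replicate 2 (0.0504) and among genes with a mean of at least 5 FPKM (0.729). Of 19 sonic hedgehog pathway genes, 6 rose and 3 fell (7 and 3 adjusted over the list alone), with a median of 0.12, an adjusted p of 0.122 and adjusted p = 0.439 with an estimated correlation, and the adjusted p was 0.00290 among genes with a mean of at least 5 FPKM and 0.00901 upward in fry. Without WT replicate 2 the median was 0.08. Chosen after their values were seen, the target genes PTCH1 and GLI1 rose by 0.77 and 0.72 and GPC3, the gene of a cell surface proteoglycan, by 1.98. NKX2-2, also in this list and 1 of the 3 that fell, had its lowest difference, -1.11. Of 36 TGF-beta and BMP pathway genes, 12 rose and 7 fell (15 and 9 adjusted over the list alone), with a median of 0.17, an adjusted p of 0.0984 and adjusted p = 0.439 with an estimated correlation, while fry called it upward (0.0179). Chosen in the same way, BMP4 rose by 1.59 and the BMP target genes ID1 and ID2 by 1.08 and 1.15, while TGFBI fell by 1.08.

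**Figure D3:**
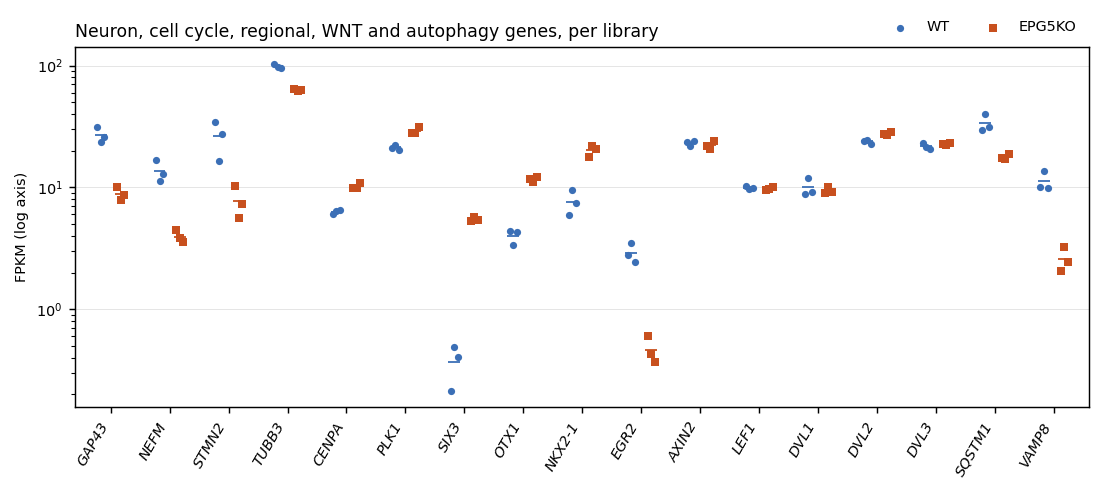
FPKM of genes of neurons, the cell cycle, brain regions, the WNT pathway and autophagy on a log axis. Each point is a library, 3 WT (circles) and 3 EPG5KO (squares) per gene, and the line is the group mean; AXIN2 lies at 23.3 and 22.1 FPKM on average in WT and EPG5KO, and EGR2 at 2.90 and 0.465 FPKM.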

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

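Removal of the length and GC trend, and camera with an estimated correlation within the block, were chosen after the data were seen. No gene called here was called in the opposite direction under any alternative, and 95 of the 109 named genes apart from EPG5 kept their direction and their side of the threshold under every alternative that gave them a value. Apart from the choice of set test, 13 of the 18 called lists kept theirs. Depth limits the low values to an unknown extent, since read totals are unknown.

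Against 2667 genes (1258 higher, 1409 lower), a mean of at least 5 FPKM gave 1570 (777 higher, 793 lower), 1564 of them among the 2667, where fewer genes were tested, and 140 past 2-fold against 276 (56 higher, 84 lower). Array weights, which rest mostly on WT replicate 3 and EPG5KO replicate 1, gave 6260 (3682 higher, 2578 lower). The replicate block gave 3676 (1861 higher, 1815 lower) and, with the length and GC trend removed, 4140 (1878 higher, 2262 lower). With a library left out, the count lay between 1489 and 2971, the higher count between 633 and 1463 and the lower count between 856 and 1534, where fewer libraries were tested. A pseudocount of 0.1 put 505 genes past 2-fold (164 higher, 341 lower), since it shrinks low values less. The other alternatives moved these counts by less than 1.5 times. In camera with an estimated correlation, 0 of 33 lists passed (1 at an unadjusted p under 0.05), and likewise 0 with the estimated correlation in the replicate block (1 at an unadjusted p under 0.05). The other alternatives called 17 to 20 lists.

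The EPG5 difference was -0.24 with array weights and lay between -0.272 (without WT replicate 2) and -0.0708 (without WT replicate 3), with adjusted p from 0.00973 to 0.756 over the alternatives. The WNT/beta-catenin target list pointed up with a mean of at least 5 FPKM (adjusted p = 0.240), where 14 members were tested, and its adjusted p lay between 0.113 and 0.857. The cytoplasmic WNT list pointed up with a mean of at least 5 FPKM (0.950), with fry (0.922), and without WT replicate 1 or 3 or EPG5KO replicate 1 or 2, with adjusted p from 0.287 to 0.999 when a library was left out. The pluripotency list turned with fry (0.367) and the epithelial list without a filter (0.581). The ribosomal list turned with quantile normalization (0.614), array weights (0.470), removal of the length and GC trend (0.537), and without WT replicate 2 or EPG5KO replicate 3, with adjusted p from 5.62e-04 to 0.911 when a library was left out. LEF1 lay between -0.0443 and 0.00231 and DVL1 between -0.144 and 0.0584 when a library was left out. Where no cause is given here, the cause was not tested. The replicate block ended the call of the hindbrain list and added those of the mitochondrially encoded list, NDUFA1, NDUFA8, COX7A2 and DCX, and changed no other call of a list with the preset correlation or of a named gene.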

Other observations

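The tests of quantile normalization, of the cell cycle list after the length and GC correction, of forebrain genes with a mean of at least 5 FPKM, of BLCAP, of the neighbours of NNAT, of imprinted genes, of direct WNT feedback genes, of FGF and ERK feedback genes and of the number of lines were chosen after the results they bear on had been seen, and the genes named in this part were chosen after their values were seen.

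Several genes that receptor tyrosine kinases and ERK induce were lower in EPG5KO. DUSP6, a phosphatase gene that limits ERK, went from 24.6 ± 0.257 to 7.25 ± 1.35 FPKM (SD, n = 3 each), and the ERK-responsive transcription factor gene ETV5 from 10.4 ± 1.07 to 3.34 ± 0.721 FPKM. A list of such genes was then written, and 6 genes whose values had been seen by then were left out of its test, although the values of the others were printed before that test was run. Of those 6, EGR1 fell by 0.59, IER3 by 0.52 and CCND1 by 0.29 besides DUSP6 and ETV5, while MYC did not pass (-0.07). Of the 17 others tested, 13 fell and 0 rose, with a median difference of -0.74, against a median of 0.02 and a 95% range from -0.08 to 0.13 over 10000 random lists matched on mean expression. SPRY4 fell by 1.31, ETV4 by 1.05 and IL17RD by 0.83, while EPHA4 (0.01) and FGFRL1 (0.06) did not pass. The list's median lay at the 0.01 percentile of the random lists, the smallest they can show, and camera gave p = 6.21e-11 with the preset and p = 0.0347 with an estimated correlation, both unadjusted. The hypothesis is that FGF or ERK signal output may be lower in the knockout line, and it was found and tested on the same data, with no technical explanation tested for it.

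The adjacent basement membrane collagen genes COL4A3 and COL4A4, which share a promoter region, rose together, from 4.02 ± 0.862 to 14.1 ± 1.00 FPKM and from 5.50 ± 1.11 to 16.1 ± 1.55 FPKM.

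The first pattern weighed is the fall of neuron genes together with the rise of cell cycle genes. After removal of the length and GC trend within the replicate block the neuron list had a median of -0.635 and the cell cycle list of 0.273, which argues against a length and GC bias as the whole cause. Quantile normalization gave -0.634 and 0.275, against -0.67 and 0.28 in the main fit. Median-ratio scaling, the test chosen in advance, had factors between 0.984 and 1.03 and moved almost nothing. Both had little to move, so neither decides about the scaling of the libraries. A single factor per library would shift both lists the same way, which their opposite signs argue against. The knockout of EPG5 and clone or culture differences unrelated to the EPG5 edit cannot be told apart, because there is 1 knockout line, and the day of the WT cells is not given.

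The second pattern is NNAT, at 2.89 FPKM in WT and 122.5 FPKM in EPG5KO. BLCAP, whose intron holds NNAT, differed by -0.346, which argues against reads shared with it, and the 76 tested genes within 5 Mb had a median of -0.0343, which argues against a gain of that region. NLRP2 is imprinted as well. Of 29 other imprinted genes tested, BLCAP among them, 2 rose and 9 fell, including SNURF (-1.26), PHLDA2 (-0.97) and FAM50B (1.00). Their median absolute difference of 0.193 lay at the 96.3 percentile of matched random lists. It was still inside the range of those lists, 0.0816 to 0.199, taken as for the FGF and ERK genes. For an absolute difference, only the upper end of the random lists bears on the question. There the 96.3 percentile went with imprinted loci that differ between the lines. The imprinted genes thus differed more than most random lists, though not beyond that range. Imprinted loci that differ between the lines may be part of the pattern, but this test does not settle it. Expression values without allele or methylation data leave that hypothesis open beside an effect of the knockout.

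The third pattern is the rise of forebrain genes. Among genes with a mean of at least 5 FPKM, 5 of 6 rose with a median of 0.688 (camera adjusted p = 2.06e-04, between 1.84e-08 and 0.404 over the alternatives), which argues against low values as the whole cause, whereas a smaller pseudocount, the test chosen in advance, enlarges low values and decided nothing. The list had a median of 1.04 after removal of the length and GC trend, which argues against that bias. Of the 9 direct WNT feedback genes tested, 0 rose and 1 fell, with a median of -0.0708 and a range from -0.53 to 0.28. They showed no rise in WNT/beta-catenin output, but they went both ways and do not settle it. Only higher output was tested as a cause, and lower output was not. Clone and knockout are joined here as well, so the pattern could come from either.

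Of the 10 splits of the 6 libraries into groups of 3, 1 split, the real one, gave 2667 genes, and the highest count of any other was 0 in limma, with up to 693 genes at an unadjusted p under 0.05. The 4 splits that part all 3 pairs of replicate numbers include the real one, and the other 3 gave 0 genes. Every other split puts libraries of both groups on each side, so the difference between the groups widens the spread within each side. Counts near 0 were thus likely there whatever the cause, and they do not show how many genes chance would give. With 10 splits the share cannot go under 0.05.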
